A study of Schizosaccharomyces pombe with 32 samples.

How the data were processed

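Total RNA of Schizosaccharomyces pombe was measured on 32 single-colour Affymetrix arrays after biotin labelling by in vitro transcription, per the labels' protocols. The stressed series held 22 arrays, from 2 cultures sampled at 11 times, and the control series held 10 arrays, from 2 untreated cultures sampled at 5 times. Series, time and culture number were read from the sample titles, which gave 16 groups of 2 arrays. Each number stood for 1 batch culture followed through time, so the numbers pair arrays within a series, and a stressed and an untreated culture share only a number. Over pairs of times, the difference between culture 2 and culture 1 correlated across probe sets with a median r of 0.707 in the control series (lowest 0.362, 10 of 10 pairs above 0.1). In the stressed series the median was 0.259 (lowest -0.369, 34 of 55 pairs above 0.1). Genes are not independent replicates in these correlations.

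The values used are the signal per probe set as the authors deposited it in the value table of the series, on a linear scale from 0.0029 to 64.6. How the authors corrected background, summarised probes and scaled arrays is not given in the sources used here, so the calibration of the signal stays unknown. The table held 4972 probe sets and no control probe sets. Array medians lay between 1.52 and 2.0 and differed by culture: 1.68 to 1.82 in stressed culture 1, 1.52 to 1.63 in stressed culture 2, 1.95 to 2.0 in untreated culture 1 and 1.71 to 1.82 in untreated culture 2. Detection calls were not used here, so the floor of the signal is unknown and a fold from a low signal has no known bound. The number of arrays, 2 per group, limits the precision of every value.

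Gene symbols came from the platform annotation. It gave 1 symbol for 2903 probe sets and several for 16, and the other 2053 were unnamed here, which does not mean that they lack a gene. By gene ID, 2900 of the 2903 matched a RefSeq gene table (assembly ASM294v3), which updated 110 symbols. No coordinates were used.

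Deposited signals were log2-transformed with no pseudocount, because none was at 0. limma 3.58.1 in R 4.3.3 fitted all 32 arrays with 1 mean per group (lmFit, eBayes, 16 residual and 3.23 prior degrees of freedom), so that all groups shared 1 estimate of the spread per probe set. All 4972 probe sets were tested. Adjusted p-values are those of limma's moderated test after Benjamini-Hochberg adjustment within each of the 21 comparisons, with a threshold of 0.05. The comparisons were each stressed time against 0 min, each untreated time against 0 min, the difference of these changes at the shared times, both series at 0 min, and stressed 60 against 15 min and 240 against 60 min. An F-test covered all 10 stressed times. A change is a log2 difference with its standard error (SE), and a mean signal carries its SD over 2 cultures. A change in 1 culture, against its own 0 min array, has no replicate and no test. The design, the alternatives, the lists and the rule for named genes were fixed before the data were examined, except where stated.

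For the lists, 25 gene lists were fixed, by name or by symbol pattern. Of 518 names, 389 were found, and 678 probe sets fell in a list. Some lists share probe sets: 5 of the 11 in the trehalose and glycerol list were in another list. Among them, ntp1 and gut2 were in the core stress list, so these lists are not separate evidence. In the proteasome list the older synonym pus1 of rpn10 also brought in pus1, a tRNA pseudouridine synthase gene. camera tested the 24 lists with at least 5 probe sets at a preset inter-gene correlation of 0.01 and with an estimated one. Adjustment ran over 240 tests for the 10 stressed times and over 264 for the other 11 comparisons. Counts within a list adjusted over the list alone are given beside those adjusted over all probe sets. List medians are given less the median of all probe sets in the same comparison, which was -0.11 at 50 and at 60 min and -0.10 at 90 min. The camera test compares the mean test statistic of a list with that of the other probe sets. Its p-values are therefore not tests of the list medians printed beside them, and a few members with large changes can weigh in them. Centring the arrays moved the median of all probe sets by over 0.1 at 0 min between the series, from -0.10 to 0.03.

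The rule for named genes took probe sets with 1 gene, an adjusted p under 0.05 and the same direction in both cultures: the 8 highest and 8 lowest at 15 min, and the 4 highest and 4 lowest at 60 min, at 240 min, in untreated cultures at 240 min, in the difference of changes at 60 min and between series at 0 min. To these came up to 4 members per list with the lowest F-test p, and any member of the core stress and antioxidant lists. Genes named outside the rule are said to have been chosen after their values were seen.

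The test was tried on simulated data for 15 min against 0 min, with 200 of 4972 probe sets changed in 10 draws. At log2 changes of 0.5, 1, 2 and 3 it recovered 1.2%, 24.2%, 70.8% and 89.8% of them, 4.9% of its calls were false, and a list shifted by 0.5 was called in 10 of 10 draws. The simulated noise was independent for each probe set and array, with no culture effect and no correlation between genes. These rates therefore do not hold for real arrays that carry either of them, and they do not check the list test against correlated genes.

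The alternatives were the culture as a block (the replicate block), the arrays of the compared groups alone, quantile normalization, median centring, leaving out the 25% of probe sets with the lowest signal, a trend in the prior variance, a minimum change of 2-fold, all 4 arrays at 0 min as reference, the direct difference between series, the culture as a random block, and leaving out each culture or each stressed 0 min array. Without a stressed culture each stressed group held 1 array, and the spread came from the untreated cultures alone. Calls of those fits are not replicated evidence on peroxide. After the values were seen, 3 fits were added. They left out the 30 min array of stressed culture 2, left out all stressed arrays at 30 min and at 90 to 240 min (called the early-array fit below), or tested probe sets with 1 symbol alone. Because the early-array fit drops the stressed times at which the cultures differed most, its spread is lowered by that choice. Its adjusted p-values may therefore be too small. It was also run with an estimated inter-gene correlation. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.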

Results

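The data follow the messenger RNA of fission yeast (Schizosaccharomyces pombe, strain JB50, a homothallic strain that can mate with itself) through 240 min of oxidative stress. Hydrogen peroxide at 0.5 mM was given to batch cultures in rich medium, and 2 stressed cultures were sampled before it, then at 5, 10 and 15 min, at 30, 50, 60 and 90 min, and hourly from 120 to 240 min. A further 2 cultures without peroxide were sampled at 0, 60, 120, 180 and 240 min. Each of the 32 arrays gave a deposited signal for 4972 probe sets, with array medians from 1.52 to 2.0. The growth notes name stressed cultures of different starting density and do not tie a density to either of those on the arrays. The comparisons ask which transcripts moved after peroxide, when, and whether untreated cultures moved too.

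Within 5 min of peroxide, transcripts of srx1, ctt1 and pyp2, chosen after their values were seen, stood higher in both stressed cultures. The change of srx1, the gene of sulfiredoxin, which restores oxidised peroxiredoxin, was 3.11 in culture 1 and 2.94 in culture 2 on the log2 scale. That of the catalase gene ctt1 was 3.05 and 2.57, and that of pyp2, a phosphatase acting on the stress kinase Sty1, was 2.16 and 2.41. The antioxidant and Pap1 target list as a whole moved less at 5 min, its median less that of all probe sets being 0.27 in culture 1 and 0.11 in culture 2, with 6 and 9 of its 25 members lower. Over both cultures it stood 0.17 above all probe sets (camera adjusted p = 3.99e-08, adjusted p = 0.369 with an estimated correlation), and 0 members passed either over all probe sets or over the list alone. At 15 min the changes were 3.02 for srx1, 3.19 for ctt1, 3.42 for pyp2 and 3.88 for lsd90. In the early-array fit, whose calls were chosen for naming after the values were seen, srx1 (adjusted p = 0.000761), ctt1 (0.0436) and pyp2 (0.0436) rose at 5 min. At 10 min lsd90, rsv2, srk1 (a kinase bound by Sty1) and etr1 had risen as well, with adjusted p from 0.00312 to 0.0413. At 15 min inv1, the invertase gene, and isp6, a vacuolar protease gene, were added (adjusted p = 0.023 and 0.0321), and mug113 fell by 0.93 (adjusted p = 0.0341). Across probe sets the changes of both cultures correlated with r = 0.35 at 5 min, 0.50 at 10 min and 0.63 at 15 min. Culture 1 at 10 min had r = 0.77 with culture 2 at 5 min, and culture 1 at 5 min had 0.62 with culture 2 at 10 min. The order of genes within these first times is therefore not firm.

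The fit of all arrays, in limma, called 0 probe sets at 5, 10 or 15 min, with 21, 66 and 149 at an unadjusted p under 0.05. The early-array fit called 4, 14 and 25. Using the arrays of the compared times alone gave 1, 0 and 11, and with the culture as a block there were 0, 0 and 2. Without stressed culture 2 the fit of all arrays gave 0, 10 and 14.

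As groups, the antioxidant and Pap1 target list stood 0.43 above all probe sets at 15 min (camera adjusted p = 1.48e-08, adjusted p = 0.37 with an estimated correlation), with 0 of 25 members past the test over all probe sets and 4 rising adjusted over the list alone. The core stress list of the Sty1 and Atf1 pathway stood 0.66 above (adjusted p = 0.00022, adjusted p = 0.61 with an estimated correlation), with 0 of 24 members called either way. Genes of trehalose and glycerol metabolism and genes of nitrogen and carbon starvation stood 0.49 and 0.27 above all probe sets (adjusted p = 0.0118 and 0.00668, and adjusted p = 0.62 and 0.37 with an estimated correlation). Iron uptake genes stood at -0.64 (adjusted p = 0.00623, adjusted p = 0.61 with an estimated correlation), with -0.24 in culture 1 and -0.68 in culture 2, and respiratory chain genes at -0.21 (adjusted p = 0.00209, adjusted p = 0.79 with an estimated correlation). The iron uptake list already stood higher in these cultures than in untreated ones at 0 min. A return from a high start can thus not be told apart from an effect of peroxide on that list. Mitosis and cell separation genes stood at -0.19 (adjusted p = 0.0415, adjusted p = 0.86 with an estimated correlation).

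Ribosome biogenesis genes, which make and process ribosomal RNA and assemble ribosomal subunits, stood at -0.35 at 15 min (adjusted p = 0.000842, adjusted p = 0.88 with an estimated correlation), and the cultures differed in when these genes moved. The median of the 48 members less that of all probe sets was -0.59 in culture 1 and -0.03 in culture 2 at 15 min, and -1.29 and -1.03 at 50 min. The RNA helicase gene dbp2, named after its values were seen, shows the same order. Its change at 15 min was -1.31 in culture 1 and 0.18 in culture 2, and at 60 min it was -3.03 and -2.36.

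At 30 min, 53 probe sets passed the test, 43 higher and 10 lower. Among those with a gene, named after their values were seen, caf5, a membrane transporter gene, rose by 4.18 ± 0.93 (SE, adjusted p = 0.0401) and per1 by 1.69 ± 0.32 (adjusted p = 0.0202). The mating pheromone gene mfm2 fell by 4.42 (SE 0.99, adjusted p = 0.0401), the iron uptake gene fio1 by 2.70 (SE 0.58, adjusted p = 0.0337) and the meiotic regulator gene mei2 by 2.26 (SE 0.54, adjusted p = 0.0482). Each of these 5 genes lost its call without the 30 min array of culture 2, and without either stressed 0 min array. At 0 min fio1 already stood higher in these cultures than in untreated ones, though without a call. A return from a high start can thus not be told apart from an effect of peroxide on fio1. Respiratory chain and mitochondrial ribosomal protein genes stood at -0.68 and -0.60 (camera adjusted p = 1.65e-10 and 4.97e-08, adjusted p = 0.61 for each with an estimated correlation). Their change lay mostly in culture 2, at -0.98 and -0.82 less the median of all probe sets, against -0.43 and -0.42 in culture 1. The 30 min array of culture 2 had a highest correlation of 0.909 with any other array, against 0.973 or more for each of the other 31, and without it 6 probe sets passed. Without either 0 min array of the stressed cultures 3 and 1 passed, without either untreated culture 21, and without stressed culture 1 or 2 there were 116 and 98. With the culture as a block 406 passed (191 higher, 215 lower), with all 4 arrays at 0 min as reference 267 (173 higher, 94 lower), and with the arrays of the compared times alone 0. With the deposited values 81.1% of the 53 calls were higher, and after quantile normalization 62.5% of 64 calls were.

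At 60 min the changes of both stressed cultures correlated across probe sets with r = 0.83, and at 50 min with 0.85. tms1, a hexitol dehydrogenase gene, rose by 4.58 ± 0.96 (SE, adjusted p = 0.0363), from a signal of 0.384 ± 0.00608 to 9.35 ± 2.35 (SD, n = 2). The small heat shock protein gene hsp16 rose by 2.57 ± 0.51 (adjusted p = 0.0318), from 3.88 ± 1.10 to 22.5 ± 0.19, and the acetyltransferase gene aca1 by 2.44 ± 0.51 (adjusted p = 0.0363). The genes that fell and met the rule were rid1, by 1.85 (SE 0.29, adjusted p = 0.00998), and rml2, a mitochondrial ribosomal protein gene, by 0.89 (SE 0.19, adjusted p = 0.0363). These 5 genes met the rule at 60 min, but each lost the call when either stressed 0 min array was left out, and all but rid1 when only probe sets with 1 symbol were tested. The call of rml2 was also lost after quantile normalization or median centring. At that time srx1, ctt1 and pyp2 still stood at changes of 3.33, 3.35 and 4.04.

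**Figure D1:**
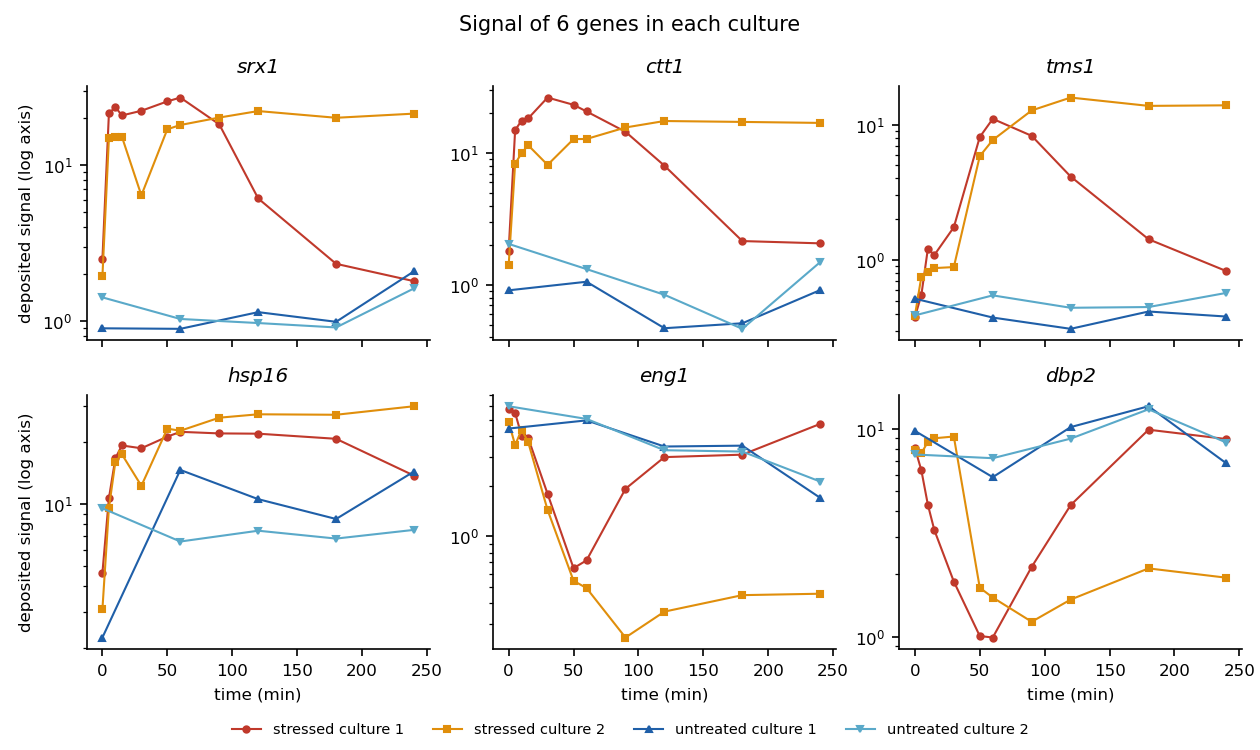
Deposited signal (log axis) against time in min for 6 genes, with 1 point per array and 1 line per culture. At 60 min srx1, ctt1, tms1 and hsp16 are above and eng1 and dbp2 below their 0 min signal in both stressed cultures, and at 240 min srx1 is at -0.47 from its 0 min value in stressed culture 1 and at 3.47 in stressed culture 2 (log2).

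In all, 27 probe sets passed at 60 min (22 higher, 5 lower) and 15 at 50 min (13 higher, 2 lower). Only the 5 genes above met the rule at 60 min, so most of these 27 calls fell on probe sets that did not meet it, such as those unnamed here. The shared spread of this fit includes the later times, at which the stressed cultures parted. With the arrays of 0 and 60 min alone 409 probe sets passed (215 higher, 194 lower), and at 50 min 560 (256 higher, 304 lower). With the culture as a block there were 54 (45 higher, 9 lower) and 52 (36 higher, 16 lower). The early-array fit called 865 at 60 min (382 higher, 483 lower) and 893 at 50 min (402 higher, 491 lower). Its spread is lowered by the choice, made after the values were seen, to drop the times at which the cultures differed most. All 27 were among the 865, but both fits use the same 0 and 60 min arrays, so this is no separate evidence. When either stressed 0 min array was left out, or only probe sets with 1 symbol were tested, 1 probe set passed at 60 min. Leaving out either untreated culture left 4, leaving out stressed culture 1 or 2 gave 318 and 239, and without the 30 min array of culture 2 there were 49. With the deposited values 81.5% of the 27 calls at 60 min were higher, and after quantile normalization 92.9% of 28 calls were.

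The genes named next, called by the early-array fit at 60 min, were chosen after their values were seen. Among the highest were lsd90 (5.81 ± 0.44, SE, adjusted p = 2.34e-06), inv1 (5.61 ± 0.44, adjusted p = 2.34e-06), the enolase gene eno102 (4.72 ± 0.65, adjusted p = 0.000382), ish1 (4.03 ± 0.54, adjusted p = 0.000297) and the metallothionein gene zym1 (3.89 ± 0.70, adjusted p = 0.00202). Among the lowest were adg1 (-3.43 ± 0.63, adjusted p = 0.00225) and the glucanase gene eng1 (-3.15 ± 0.25, adjusted p = 2.34e-06), which serve cell separation, dbp2 (-2.69 ± 0.42, adjusted p = 0.000843) and slp1, an activator of the anaphase-promoting complex (-2.65 ± 0.31, adjusted p = 0.000107).

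At 60 min 10 of the 24 tested lists were called, 4 above and 6 below all probe sets. The core stress list stood 1.09 above (camera adjusted p = 0.000165, adjusted p = 0.61 with an estimated correlation). Of its 24 members 1, tms1, rose and 3 did adjusted over the list alone, and 10 rose in the early-array fit. The antioxidant list stood 0.71 above (adjusted p = 2.73e-06, adjusted p = 0.46 with an estimated correlation). Of its 25 members 0 passed over all probe sets, 9 rose and 1 fell adjusted over the list alone, and 9 rose and 1 fell in the early-array fit. Those that rose there included the glutathione transferase genes gst2 (2.40 ± 0.54, SE, adjusted p = 0.00743) and gst3 (2.52 ± 0.41, adjusted p = 0.00106) and the glutathione peroxidase gene gpx1 (1.46 ± 0.37, adjusted p = 0.0134), and the one that fell was apt1 (-1.32 ± 0.41, adjusted p = 0.0375). Ubiquitin and autophagy genes stood 0.66 above (adjusted p = 0.000239, adjusted p = 0.61 with an estimated correlation), with 0 of 28 called either way and 7 rising in the early-array fit, among them atg9 (1.14 ± 0.24, adjusted p = 0.00556). Trehalose and glycerol genes stood 0.68 above (adjusted p = 0.00492, adjusted p = 0.61 with an estimated correlation), with 0.55 in culture 1 and 1.11 in culture 2. Of the 11 members 0 were called either way and 3 rose in the early-array fit. These included the trehalase gene ntp1 (2.09 ± 0.45, adjusted p = 0.00587), which is also in the core stress list.

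Ribosome biogenesis stood at -1.15 at 60 min (camera adjusted p = 6.78e-13, adjusted p = 0.61 with an estimated correlation). Of its 48 members 0 passed over all probe sets, 26 fell adjusted over the list alone and 34 fell in the early-array fit, such as bms1 (-1.26 ± 0.25, SE, adjusted p = 0.0033) and utp10 (-1.28 ± 0.24, adjusted p = 0.00265). RNA polymerase I and III subunits stood at -0.98 (adjusted p = 3.5e-06, adjusted p = 0.61 with an estimated correlation), with 0 of 24 called either way and 13 falling in the early-array fit, among them nuc1, the largest subunit of RNA polymerase I (-1.81 ± 0.28, adjusted p = 0.000711). Mitosis and cell separation genes stood at -1.10 (adjusted p = 7.98e-06, adjusted p = 0.61 with an estimated correlation), with 0 of 26 past the test over all probe sets, 4 falling adjusted over the list alone and 13 in the early-array fit. The chaperonin list stood at -0.44 (adjusted p = 0.00488, adjusted p = 0.61 with an estimated correlation) and translation factors at -0.25 (adjusted p = 0.0259, adjusted p = 0.73 with an estimated correlation), which lay in culture 1, at -0.47 against -0.01 in culture 2. The median of cytosolic ribosomal protein genes stood at only -0.03, with 0 of 117 called either way and 3 falling in the early-array fit. The camera test of this list, which is not a test of the median, gave an adjusted p of 0.00275, and 0.88 with an estimated correlation.

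For the other 14 lists tested no shift was called at 60 min. The adjusted p was 0.77 for heat shock proteins, 0.0571 for the proteasome, 0.997 for glycolysis, 0.83 for the respiratory chain, 0.27 for mitochondrial ribosomal proteins, 0.34 for amino acid synthesis and 0.44 for sulfur assimilation. It was 0.997 for iron uptake, 0.73 for histones, 0.88 for G1/S genes, 0.19 for DNA repair, 0.88 for mating, 0.44 for starvation genes and 0.43 for cytoskeleton and secretion genes. The Tf2 retrotransposon list held 1 probe set, with a change of 1.26, and was not tested by camera.

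**Figure D2:**
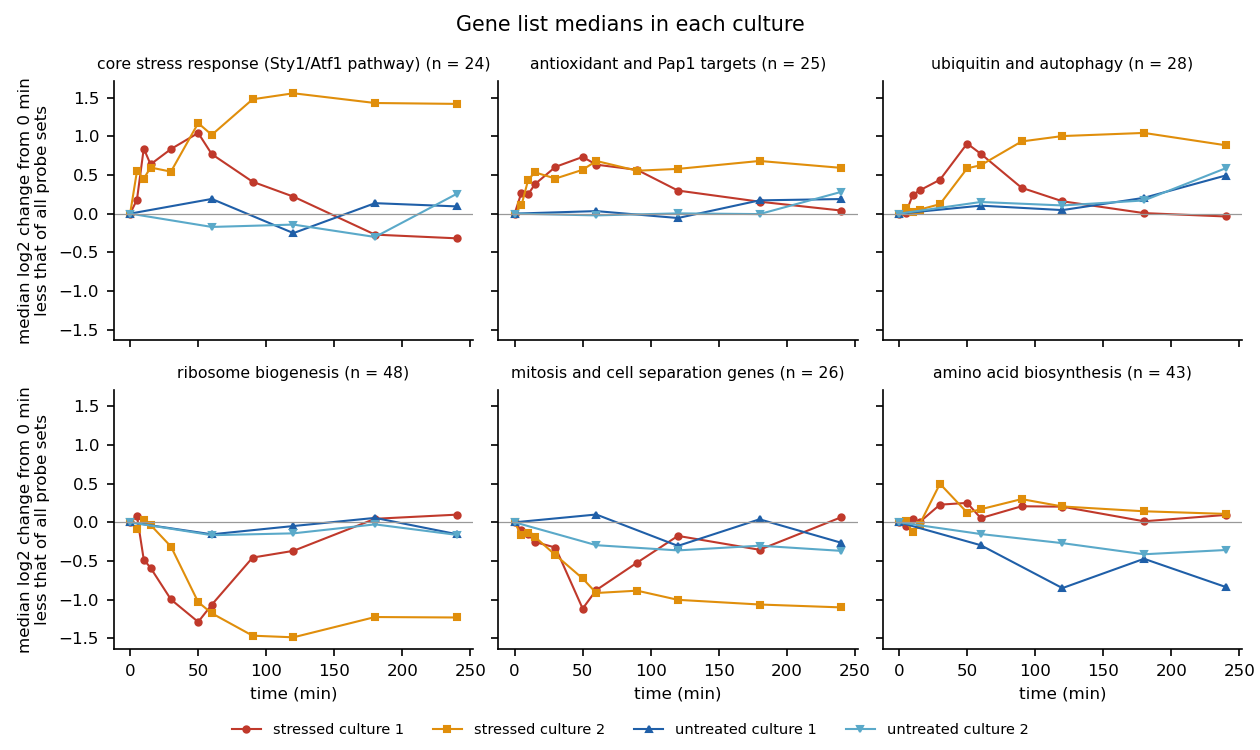
Median log2 change from each culture's own 0 min array, less the median of all probe sets, against time in min, for 6 gene lists with 1 line per culture and the number of probe sets in each title. At 240 min ribosome biogenesis is at 0.10 in stressed culture 1 and at -1.23 in stressed culture 2, and amino acid biosynthesis is lowest in both untreated cultures, at -0.84 and -0.36.

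Against 15 min, the 60 min profile had lower ribosome biogenesis, RNA polymerase I and III, and mitosis genes. Their lists stood at -0.78, -0.71 and -0.48 (camera adjusted p = 1.85e-11, 1.22e-05 and 5.92e-05, adjusted p = 0.79 for each with an estimated correlation), and ubiquitin and autophagy genes stood 0.41 above (adjusted p = 0.00135, adjusted p = 0.81 with an estimated correlation). At 15 min ribosome biogenesis stood at -0.59 in culture 1 and -0.03 in culture 2, and at 60 min at -1.07 and -1.18. limma called 0 single probe sets, with 359 at an unadjusted p under 0.05, 183 in the early-array fit, and 0 both with the arrays of these times alone and with the culture as a block. Without stressed culture 1 or 2 it called 114 and 48.

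After 60 min the stressed cultures parted. In culture 1 the early genes returned toward their 0 min signal: by 240 min its change was -0.47 for srx1, 0.19 for ctt1, -0.23 for pyp2 and -0.03 for nuc1, while tms1 and hsp16 stood at 1.13 and 1.56. In culture 2 the changes at 240 min were 3.47 for srx1, 3.59 for ctt1, 4.03 for pyp2, -1.84 for nuc1, 5.16 for tms1 and 3.26 for hsp16. These are values of 1 array each, with no test within a culture. The number of probe sets at least 2-fold from the culture's own 0 min array was 1006 in culture 1 and 935 in culture 2 at 50 min, and 116 and 1240 at 240 min.

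**Figure D3:**
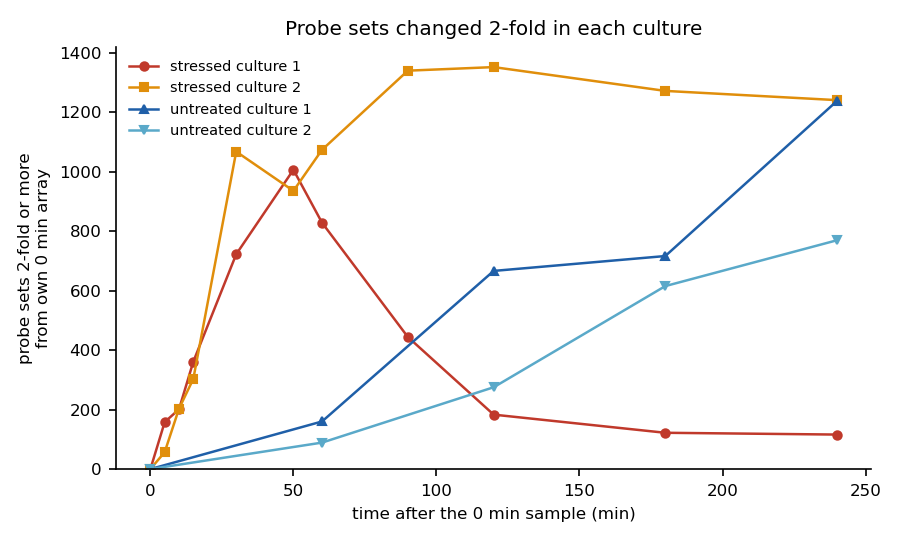
Number of probe sets at least 2-fold from the culture's own 0 min array against time in min, with 1 line per culture. Stressed culture 1 is highest at 50 min, at 1006, and ends at 116, while stressed culture 2 is at 1351 at 120 min and the untreated cultures end at 1237 and 769.

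Across probe sets the changes of both stressed cultures at the same time had r = 0.85 at 50 min, 0.83 at 60 min, 0.62 at 90 min, 0.67 at 120 min, 0.29 at 180 min and 0.04 at 240 min. The change of culture 2 at 240 min correlated with that of culture 1 at 50 min with r = 0.89. Genes are not independent replicates here, and these pairs share no array.

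Some list medians, chosen after their values were seen, parted in the same way. At 120 min ribosome biogenesis stood at -0.37 in culture 1 and -1.49 in culture 2, less the median of all probe sets, and at 240 min at 0.10 and -1.23. The core stress list stood at -0.32 in culture 1 and 1.42 in culture 2 at 240 min, and the ubiquitin and autophagy list at -0.04 and 0.88. Others did not part in this way, such as the respiratory chain at -0.24 in culture 1 and -0.12 in culture 2, amino acid synthesis at 0.10 and 0.11, mating genes at 0.06 and 0.13 and iron uptake at -0.27 and -0.57. Averaged over both, 13 of 24 lists were called at 240 min, among them ribosome biogenesis (-0.51, camera adjusted p = 2.43e-07, adjusted p = 0.72 with an estimated correlation) and the proteasome (0.25, adjusted p = 0.00117, adjusted p = 0.61 with an estimated correlation). The proteasome call was lost without culture 1 (adjusted p = 0.0777) and without culture 2 (adjusted p = 0.418). These fits held 1 array per stressed group, with the spread taken from the untreated cultures, so their list calls rest on no replicate of stress.

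Over both cultures 16 probe sets passed at 90 min, 8 at 120 min, 2 at 180 min and 1 at 240 min, and all of them were higher. Leaving out either stressed culture left 1 array in each stressed group, and the spread then came from the untreated cultures alone. Counts without a stressed culture thus rest on no replicate of stress. Leaving out either untreated culture gave 3, 3, 2 and 2, and leaving out either stressed 0 min array gave 1, 1, 1 and 0. With the culture as a block the counts were 38 (28 higher, 10 lower), 11, 4 and 2. Within single cultures the 2-fold changes at 240 min went both ways, with 54 probe sets higher and 62 lower in culture 1. In culture 2 there were 611 higher and 629 lower, so the late calls do not show that late changes were rises only. The single call at 240 min was a probe set unnamed here. No named gene met the rule at 240 min. For 240 against 60 min limma called 0 probe sets, with 109 at an unadjusted p under 0.05, 1 with the culture as a block, 0 with the arrays of both times alone, 2 without culture 1 and 367 without culture 2. The F-test over all 10 stressed times called 24 probe sets, 594 without culture 1, 167 without culture 2 and 4 without either untreated culture. Without the 0 min array of stressed culture 1 or 2 it called 5 and 8, and with the culture as a block 51.

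The untreated cultures also changed with time. By 240 min some genes with meiotic names had risen, among them meu27 by 5.27 ± 0.71 (SE, adjusted p = 0.000116), mug95 by 4.92 ± 0.70 (adjusted p = 0.000217) and rec10, a component of meiotic chromosome axes, by 4.61 ± 0.66 (adjusted p = 0.000217). The gluconeogenic gene fbp1, which is repressed by glucose, rose by 3.99 ± 0.61 (adjusted p = 0.000463), from 0.281 ± 0.0413 to 4.64 ± 1.90 (SD, n = 2). The malic enzyme gene mae2 fell from 12.5 ± 0.534 to 1.38 ± 0.469, a change of -3.23 ± 0.32 (adjusted p = 7.02e-06). The serine synthesis gene ser2 (-2.90 ± 0.56, adjusted p = 0.00281), jmj4 (-2.57 ± 0.48, adjusted p = 0.00204) and the siderophore transporter gene str1 (-2.56 ± 0.73, adjusted p = 0.032) fell too. Of these 8 genes, fbp1, ser2 and str1 lost the call when either untreated culture was left out, and jmj4 when culture 1 was.

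**Figure D4:**
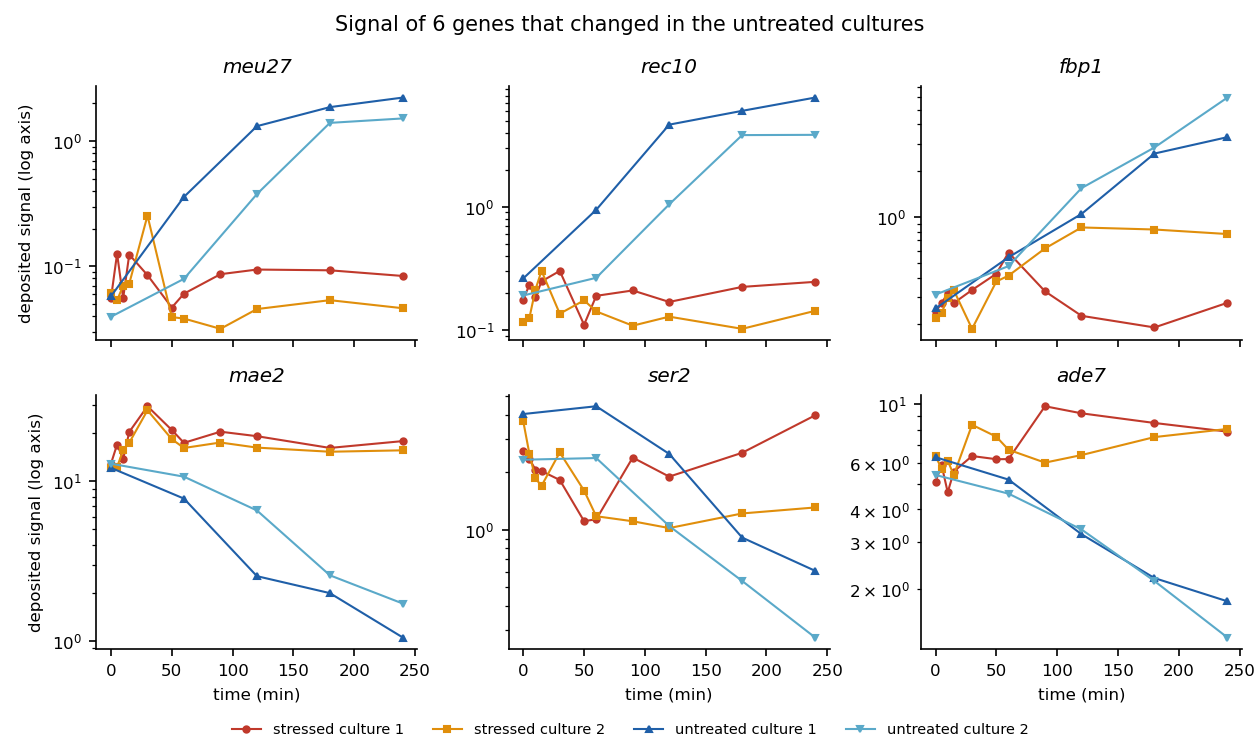
Deposited signal (log axis) against time in min for 6 genes that passed the test in the untreated cultures at 240 min, with 1 point per array and 1 line per culture. Between 0 and 240 min the mean signal of untreated cultures goes from 0.226 to 5.77 for rec10 and from 12.5 to 1.38 for mae2, while mae2 in the stressed cultures changes by 0.47 and 0.37 (log2).

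At 240 min the lists of amino acid synthesis, glycolysis and sulfur assimilation stood below all probe sets in untreated cultures, and further below in culture 1 than in culture 2. Their medians were -0.84, -0.93 and -1.11 in culture 1 and -0.36, -0.39 and -0.84 in culture 2. Lists outside biosynthesis were lower too in culture 1, with cytoskeleton and secretion genes at -0.77 and heat shock proteins at -0.53, against -0.02 and -0.36 in culture 2. Over both cultures these stood at -0.54 (camera adjusted p = 0.0261, adjusted p = 0.79 with an estimated correlation) and -0.41 (adjusted p = 0.0685). Of 17 cytoskeleton and secretion genes 2 fell, 2 adjusted over the list alone. Amino acid synthesis stood at -0.70 (camera adjusted p = 4.94e-09, adjusted p = 0.48 with an estimated correlation). Of its 43 members 12 fell, 17 adjusted over the list alone, and 0 rose, with arg12 at -1.31 ± 0.26 (SE, adjusted p = 0.00293) and his4 at -0.95 ± 0.24 (adjusted p = 0.0155). Glycolysis and fermentation stood at -0.63 (adjusted p = 8.52e-06, adjusted p = 0.56 with an estimated correlation). Of its 13 members 6 fell, 7 adjusted over the list alone, led by the hexokinase gene hxk2 (-1.51 ± 0.27, adjusted p = 0.00182). Sulfur assimilation stood at -0.77 (adjusted p = 0.00149, adjusted p = 0.30 with an estimated correlation), and 3 of its 8 members fell, 4 adjusted over the list alone, with sua1 at -1.90 ± 0.49 (adjusted p = 0.0185). Mating and sexual differentiation genes stood 0.48 above all probe sets (adjusted p = 0.0194, adjusted p = 0.79 with an estimated correlation), mostly from culture 2, at 0.86 against 0.14 in culture 1. Of its 31 members 6 rose and 1 fell, 7 and 1 adjusted over the list alone, with mei4, a meiotic transcription factor gene, at 1.65 ± 0.31 (adjusted p = 0.00205). The pheromone gene mfm3 (1.69 ± 0.29, adjusted p = 0.00124) and the pheromone receptor gene mam2 (3.21 ± 0.58, adjusted p = 0.00162) were chosen after their values were seen.

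The number of probe sets called in untreated cultures was 2 at 60 min, 56 at 120 min (43 higher, 13 lower), 275 at 180 min (182 higher, 93 lower) and 490 at 240 min (293 higher, 197 lower). With the culture as a block it was 21, 158, 604 and 950. At 240 min leaving out untreated culture 1 left 37 calls and leaving out culture 2 left 134, and at 180 min there were 39 and 40.

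The difference between stressed and untreated changes tests whether a transcript moved otherwise with peroxide than without. At 60 min rid1 differed by -2.39 ± 0.41 (SE, adjusted p = 0.0323): its change was -1.60 and -2.11 in the stressed cultures and 0.54 on average in the untreated ones. This call was lost without stressed culture 2 or either untreated culture. At 240 min the largest differences, named after their values were seen, lay in genes that moved in the untreated cultures. mae2 differed by 3.65 ± 0.46 (adjusted p = 0.000809) and the purine synthesis gene ade7 by 2.42 ± 0.35 (adjusted p = 0.00144). meu27 differed by -5.17 ± 1.0 (adjusted p = 0.0107), mug95 by -5.08 ± 0.99 (adjusted p = 0.0111) and mde6 by -3.77 ± 0.55 (adjusted p = 0.00144). The changes of meu27 in the stressed cultures were 0.59 and -0.40. The calls of mae2, meu27 and mug95 were lost without either stressed culture, and that of mde6 without stressed culture 2.

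As lists, amino acid synthesis and glycolysis stood 0.64 and 0.72 above all probe sets in the difference at 240 min (camera adjusted p = 2.32e-09 and 1.79e-06, adjusted p = 0.48 and 0.54 with an estimated correlation). Of 43 amino acid members 1 was higher, arg12 (1.96 ± 0.36, SE, adjusted p = 0.00744), and 7 were adjusted over the list alone. Of 13 glycolytic members 0 passed over all probe sets and 5 were higher adjusted over the list alone. At 60 min the difference for ribosome biogenesis was -0.96 (adjusted p = 4.94e-09, adjusted p = 0.81 with an estimated correlation) and for the antioxidant list 0.65 (adjusted p = 3.04e-05, adjusted p = 0.48 with an estimated correlation).

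The test of the difference called 2 probe sets at 60 min, 13 at 120 min, 72 at 180 min (19 higher, 53 lower) and 74 at 240 min (20 higher, 54 lower). With the culture as a block there were 14, 85, 229 and 313, and the early-array fit called 163 at 60 min. With the arrays of the compared groups alone the counts were 131, 5, 27 and 0. Without stressed culture 1 they were 70, 247, 240 and 142, and the direction turned, with 159 of the 240 higher and 81 lower at 180 min and 99 of the 142 higher and 43 lower at 240 min. Without stressed culture 2 they were 97, 12, 0 and 34, and without untreated culture 1 they were 0, 0, 17 and 15. At 120 min 46.2% of the calls were higher with the deposited values, 31.8% after quantile normalization, and after median centring 3 of 12 were.

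Before peroxide, both series were compared at 0 min. Iron uptake genes stood 0.72 above all probe sets in the cultures to be stressed (camera adjusted p = 2.19e-13, adjusted p = 0.024 with an estimated correlation). Of the 13 members 0 passed over all probe sets and 3 were higher adjusted over the list alone, and the ferroxidase gene fio1 and the permease gene fip1, which together import iron, stood at 2.37 ± 0.58 and 2.72 ± 0.56 (SE, adjusted p = 0.61 and 0.57). Core stress genes stood 0.28 above (adjusted p = 0.000461, adjusted p = 0.80 with an estimated correlation) and mating genes at -0.25 (adjusted p = 0.00184, adjusted p = 0.54 with an estimated correlation). The spread in these list tests came from arrays of all times. Differences between cultures recurred over time, with a median r of 0.707 in the control and 0.259 in the stressed series. No list was tested at 0 min with the culture as the unit, so the p-values of these lists, iron uptake included, may be too small. limma called 0 single probe sets, with 65 at an unadjusted p under 0.05, 0 with the culture as a random block and 21 with the 0 min arrays alone. A fixed culture block, which leaves the difference between cultures of 1 series out of the spread, called 22.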

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

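The tests of array scaling and of the same rise in stressed cultures below were chosen after the results were seen. The difference between the change in stressed and in untreated cultures was tested directly, and it called 2 probe sets at 60 min, 13 at 120 min, 72 at 180 min and 74 at 240 min. At 60 min the change of rid1 differed by -2.39 ± 0.41 (SE, adjusted p = 0.0323).

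Among 134 genes named for meiotic expression (the mug and meu symbols, not a list fixed beforehand), 20 rose and 0 fell in untreated cultures at 240 min in limma, against 156 and 118 of 2899 named genes, and in the difference of changes 8 were lower and 0 higher. Their median stood 0.47 and 0.388 above that of all probe sets in untreated cultures 1 and 2, at percentiles 93.5 and 99.9 among 10000 random lists of like size and level, so in culture 1 a shift of the whole set is not shown beyond chance. Quantile normalization lowered these medians to 0.235 and 0.197. No chance range is given for the lowered values, so array scaling stays open for a part or the whole of the shift. In stressed culture 2 their median stood 0.123 above that of all probe sets, but at -0.003 after quantile normalization, and in culture 1 it stood at -0.003 and 0.04, at percentiles 67.0 and 62.6 among random lists, so neither is shown beyond chance and a smaller shift stays open. A candidate biological explanation is that nutrients ran lower in the untreated cultures, in which a strain that mates with itself may enter meiosis, while stressed cultures grew less, but no density or nutrient value was used here to test it.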

How the results depend on the processing

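The early-array fit, the fit without the 30 min array of stressed culture 2 and that on probe sets with 1 symbol were chosen after the data were seen. Counts below are of probe sets, for the comparison with 0 min unless stated, and the cause of a moved count was not tested unless the number of arrays or probe sets gives it.

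With the replicate block (each culture as a block) the stressed counts were 2 at 15 min, 406 at 30, 52 at 50, 54 at 60, 38 at 90, 4 at 180 and 2 at 240 min, with 1 for 240 against 60 min and 51 in the F-test. The untreated counts were 21, 158, 604 and 950 at 60 to 240 min, those of the difference 14, 85, 229 and 313, and that at 0 min 22. The other counts stayed within 1.5 times.

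With the arrays of the compared groups alone the stressed counts were 1 at 5 min, 11 at 15, 0 at 30, 560 at 50, 409 at 60, 47 at 90, 0 at 180 and 0 at 240 min. Untreated counts were 9 at 60 and 853 at 180 min, those of the difference 131, 5, 27 and 0, and that at 0 min 21. With all 4 arrays at 0 min as reference the stressed counts were 2 at 15 min, 267 at 30, 202 at 50, 205 at 60, 87 at 90, 31 at 120, 7 at 180 and 3 at 240 min, and the F-test gave 53.

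Quantile normalization gave 1 at 15 min, 4 at 180 min, 22 for the difference at 120 min and 1 for 240 against 60 min. Median centring gave 1 at 15 min, 30 at 90, 5 at 180 and 1 for 240 against 60 min. Without the 25% of probe sets with the lowest signal, the stressed counts were 1 at 15 min, 34 at 30 and 5 at 180 min, the untreated ones 1, 25 and 161 at 60 to 180 min, and the differences 46 at 180 and 29 at 240 min. A trend in the prior variance gave 27 at 90 min, 5 at 180 min and 20 for the difference at 120 min. A minimum of 2-fold moved no count by over 1.5 times. The direct difference between series gave 235, 474, 684 and 747 at 60 to 240 min, and 291, 591, 770 and 865 with the culture as a random block.

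The early-array fit gave 4, 14 and 25 at 5 to 15 min, 893 at 50 and 865 at 60 min, 183 for 60 against 15 min, 8, 100, 477 and 848 in untreated cultures and 163 for the difference at 60 min. On probe sets with 1 symbol the stressed counts were 5 at 30 min, 1 at 50, 1 at 60 and 0 at 90, 120, 180 and 240 min. The other counts there were 1 for 240 against 60 min, 1 in the F-test, 27, 150 and 300 in untreated cultures at 120 to 240 min, and 1, 4 and 42 for the differences at 60 to 180 min. Calls on unnamed probe sets leave these counts by construction.

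Leaving out 1 culture, 1 stressed 0 min array or the 30 min array of stressed culture 2, where the lone array of a group is assumed to vary like the others, gave from 0 to 0 calls at 5 min, 0 to 10 at 10 min, 0 to 14 at 15 min, 1 to 116 at 30 min, 1 to 372 at 50 min, 1 to 318 at 60 min, 1 to 575 at 90 min, 1 to 610 at 120 min, 1 to 458 at 180 min and 0 to 393 at 240 min. In untreated cultures the ranges were 0 to 4, 4 to 66, 39 to 348 and 37 to 671, and for the differences 0 to 97, 0 to 247, 0 to 240 and 15 to 142. The F-test ranged from 4 to 594, 60 against 15 min from 0 to 114, 240 against 60 min from 0 to 367, and 0 min between series stayed at 0. The number of gene lists called ranged from 7 to 10 at 15 min, 7 to 11 at 60 min and 4 to 14 at 240 min. With an estimated inter-gene correlation it was 0 at each of these times, against 8, 10 and 13 with the preset one, and 0 at 15 and 60 min in the early-array fit.

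Of the single-gene and per-array values under all alternatives, 2689 stayed the same, which for a gene means the same sign and side of the threshold. A further 222 passed the threshold, 154 no longer did, and 32 were marked as moved. For a gene this mark means that its change switched sign and was called in neither fit. No called value changed sign. Genes that the rule named for a call had to move the same way in both cultures, so leaving out a culture could hardly reverse them. Values called in neither fit count as the same when their sign stayed, so the 2689 do not show how firm the calls are. No signal over background is known for these arrays, so what the lowest signals limit stays open.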

Other observations

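Of the tests below, those of array scaling, of growth for the whole of the change or for most of its probe sets and of a wrong time label were chosen after the results were seen, and the genes and lists here were chosen after their values were seen. In untreated cultures at 240 min some stress-linked genes rose without peroxide. These were the heat shock gene hsp9 (1.24 ± 0.35, SE, adjusted p = 0.0321), the Pap1 regulator gene hba1 (1.2 ± 0.29, adjusted p = 0.0139), the drug exporter gene pmd1 (2.09 ± 0.44, adjusted p = 0.00522) and the dihydroxyacetone kinase gene dak2 (1.23 ± 0.38, adjusted p = 0.0472). As a list, antioxidant genes and Pap1 targets, which include hba1 and pmd1, stood 0.17 above all probe sets (camera adjusted p = 0.311), with 3 of 25 rising and 0 falling, and 4 rising and 1 falling adjusted over the list alone. Core stress genes stood only 0.08 above all probe sets (camera adjusted p = 0.45), with 3 of 24 rising and 0 falling, and 3 rising and 1 falling adjusted over the list alone. Ubiquitin and autophagy genes stood 0.55 above (adjusted p = 0.0411, adjusted p = 0.87 with an estimated correlation), with 2 of 28 rising and 1 falling, and 4 and 1 adjusted over the list alone. The untreated cultures differed in respiratory chain genes, whose median less that of all probe sets was -0.73 in culture 1 and 0.19 in culture 2.

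Stressed culture 2 kept its changed profile from 90 to 240 min while stressed culture 1 returned, and array scaling is argued against, because after quantile normalization the change at 240 min still had an SD 2.67 times as large in culture 2 as in culture 1. Each of the 5 lists at least 2-fold from all probe sets in culture 2 lay beyond all untreated medians up to 240 min. The distance was at least 1.84 times the largest difference of the same list between untreated cultures at one time (ribosome biogenesis at -1.23, against untreated medians from -0.17 to 0.06). These lists were picked by the same culture 2 values, which favours a distance, and some share genes. For these lists culture 2 moved further than the untreated cultures did. Over all probe sets, its changes at 90 and 240 min had r = 0.91 and 0.89 with culture 1 at 50 min of peroxide. With the mean untreated change its 240 min change had r = 0.36, against 0.77 between the untreated cultures at 240 min. Growth as in the untreated cultures up to 240 min is thus argued against as the whole of the change. As a part it could hold (r = 0.36 across probe sets with the mean untreated change), and for most of the 1240 probe sets at least 2-fold changed it stays open, as 46.3% had a mean untreated change of at least 0.5 (log2) in the same direction, against 69.6% and 87.4% of either untreated culture against the other. Late labels of culture 2 on arrays of culture 1 at 50 and 60 min are argued against. The difference between these arrays followed that between the cultures at 0 to 15 min with r = 0.47. Genes are not independent replicates in any of these r. Whether earlier samples of culture 2 lay under its late labels was not tested. Its 180 and 240 min arrays were the closest pair of arrays, with a median absolute log2 difference of 0.074. Beyond growth up to 240 min, no biological explanation was tested, because the labels do not tie the starting density of a culture to its number.

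The 30 min array of stressed culture 2 stood apart from its neighbours in time. Another time point of the same series under its label is argued against only for an array as good as the others, because its highest correlation with any other array was 0.909, against at least 0.973 for each other array. A wrong label on an array of poor quality stays open, as it could give the same low correlation. A distortion that depends on signal level is argued against as well, since removing a smooth trend on level lowered the SD of its deviation from the 15 and 50 min arrays by 2.20%. A transient change at 30 min in both stressed cultures stays open, as the deviations of both cultures correlated with r = 0.50 across probe sets, and a change in RNA quality or labelling of this 1 array may also account for it and was not tested.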
